A study of Mus musculus with 36 samples.

How the data were processed

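Gene expression of sorted mouse cells was measured on 36 Affymetrix whole-transcript mouse arrays. Per the labels' protocols, yolk sacs and fetal livers were digested with collagenase, bones were crushed and lungs were flushed, and cells were purified by flow cytometry before RNA was isolated. Per the series' design text, the RNA was amplified before hybridisation. Donor and wild-type cells carried congenic CD45 markers that told them apart from cells of the recipient. Markers used in the sorts beyond these are not given in the sources used here.

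The table deposited by the authors holds log2 values of 35556 probe sets, normalised by RMA per the submitters' processing notes, with no version stated. RMA corrects the background of each array, forces the probes of all arrays to a common distribution and summarises them per probe set. A shift shared by most genes of a sample is removed by that step, and small folds of dim genes are compressed towards 0. The columns were used as deposited, and 0 columns belonged to samples outside the series.

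Probe sets were named through the platform annotation held by GEO, which can be old. Of all probe sets 21789 had 1 gene symbol, 1621 had several and 12146 had no entry. Only those with 1 symbol were used. Symbols were updated by Entrez identifier through the RefSeq genes of mouse assembly GRCm38.p6, used for names only: 21698 matched and 91 kept the older symbol. For 999 genes with several probe sets the one with the highest mean over all arrays was kept, which left 19938 genes. A gene was tested where it exceeded the median of the table, 4.623 on the log2 scale, in at least 4 arrays. This left 12244 genes. Probe sets of closely related genes, such as members of the stefin, globin or MHC class II families, can share signal, and their values are less certain.

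Samples were grouped by their titles into 9 groups of 4. A linear model with 1 mean per group was fitted to all 36 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a constant prior), so that all groups shared 1 estimate of the spread per gene. There were 18 contrasts between groups and 3 interaction contrasts, which ask whether the change over transfer differed between origins. P-values were adjusted by the Benjamini-Hochberg method within each contrast, and a gene was called at an adjusted p under 0.05. Fold changes are given on the log2 scale ± standard error or as 2 to the power of that value, with the lower group mean replaced by the median of the table where it lay under it, and levels as mean ± SD. Differences of the profile distance between groups were tested by exact two-sided permutation.

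Lists of genes were tested with camera in limma at a preset correlation of 0.01 between genes, and again with an estimated correlation, adjusted over the lists within a contrast. The 26 lists held 484 entries, matched by symbol to the genes tested. They covered alveolar macrophage markers, lipid handling, cholesterol synthesis, monocyte markers, tissue and fetal macrophage markers, cell cycle, MHC class II, interferon response, inflammatory mediators, GM-CSF signalling, fetal growth, Hox and adult haematopoietic genes, scavenger receptors, lysosome, early response and sex-linked genes. The others held markers of cells that a sort could carry along: neutrophil, erythroid, B, T and NK, dendritic, eosinophil with mast cell and basophil, lung epithelium, yolk sac endoderm with hepatocyte, endothelium and progenitors. Beside each list, counts adjusted over the list alone are given.

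The groups, tests, lists, alternatives and the rule for named genes were fixed before the data were examined. Under that rule the text names a panel (Pparg, Siglecf, Car4, Fabp4, Marco, Itgax, Csf2rb, Ly6c2, Ccr2, Cx3cr1 and Timd4), of which Ly6c2 had no probe set with 1 symbol and 10 were measured. A further gene of the panel is not reported here. The rule also names, per contrast, up to 8 called genes with the largest rise and 8 with the largest fall whose groups do not overlap, fewer in that order where space asks, leaving out predicted and small RNA genes by their symbols. Per list it names up to 4 members with the lowest adjusted p, and other members with their values alone. Where 12 or fewer genes were called, all are named. The genes kept from the overlap of origin differences, such as Rps4l, Igf2bp3, Napsa and Apoc1, and genes in the plots of derived groups outside the rule were chosen after their values were seen.

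The fit and the list test were tested on simulated data of 12244 genes with the real means and spread. In a simulation of FL- against BM-derived macrophages, 88% of genes changed by a log2 fold of 1 were recovered and 100% of those changed by 2, with 14 false calls (6.93%). In a simulation of fetal liver against bone marrow monocytes these were 89% and 99%, with 8 false calls (4.08%). In the same comparison camera called 5 of 5 shifted lists and 0 of 20 unshifted ones, with either correlation. The simulated genes varied independently, so this does not test lists whose genes vary together. Each simulated gene had the same spread in all groups, so the false calls under unequal spread were not tested either. The number of arrays limits the precision.

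Alternatives were cyclic loess between arrays, eBayes with a trend and robust settings, the mean of all probe sets of a gene, no filter on dim genes, only the groups compared in the fit, the replicate number as a block, an estimated correlation, and leaving out each array in turn. A covariate for sex and a fit without 3 arrays that stood apart were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15. Scan dates and batches are not given in the sources used here, and scanner files were not used here.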

Results

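Gene expression was measured on 36 arrays of sorted mouse cells in 9 groups of 4 samples. The study placed cells of different origin in the airways of newborn mice that lack Csf2rb, the beta chain of the receptor for the growth factor GM-CSF. Alveolar macrophages, the phagocytes of the air spaces, depend on that factor. The 4 donor populations were also profiled before transfer. They were monocytes from adult bone marrow (mice of 6 to 12 weeks), monocytes from fetal liver (stage E15.5), macrophages from yolk sac (stage E12.5) and alveolar macrophages washed from adult lungs. Each population was given through the nose, and its descendants were sorted from lung lavage 6 weeks later. They are called BM-derived, FL-derived, YS-derived and AM-derived macrophages. Alveolar macrophages of untreated wild-type mice aged 6 weeks served as controls. The comparisons address how far each precursor takes on the profile of a resident alveolar macrophage in the lung, and what of its origin stays visible.

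Arrays of the same group resembled each other closely. The mean correlation of an array with the other arrays of its group ranged from 0.963 to 0.982 across genes, and the median log2 value of an array ranged from 4.54 to 4.73. The first principal component held 53.0% of the variance and separated the 3 precursor groups from all 6 groups of alveolar macrophages. The second held 19.4% and the third 4.56%. A total of 12244 genes were tested. Where 1 group's mean lay under the median of the table (4.62), the fold is a lower bound against that median, marked "at least", while log2 differences are as fitted and rest on a dim probe set. A mean just above that median is dim as well, so a fold against it is approximate. This holds for Mrc1 in bone marrow monocytes and Chil3 in fetal liver monocytes. The labels call the 4 samples of a group biological replicates. The p-values rest on the spread between samples within groups, estimated per gene over all 9 groups together. Where a gene varied more in the groups compared than in the others, that estimate is too small for them. The number of arrays limits the precision.

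**Figure D1:**
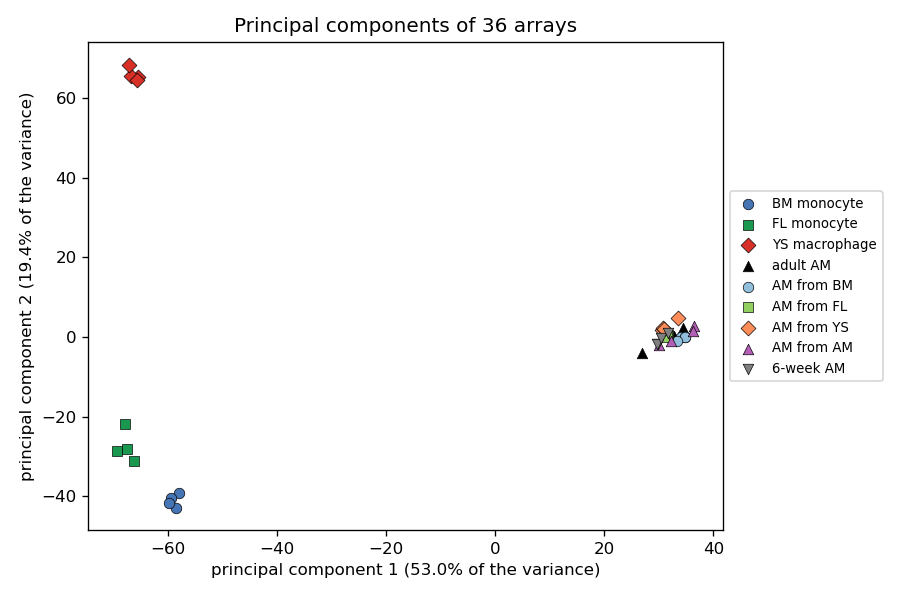
Positions of the 36 arrays on the leading principal components of the log2 expression values (arbitrary units, share of variance in percent on each axis), 1 point per array and 1 colour per group. The 3 precursor groups lie apart from each other, while the alveolar macrophage groups lie close together, with 53.0% of the variance on the first component.

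Fetal liver and bone marrow monocytes were compared to show how the fetal and the adult monocyte differ before transfer. Fetal liver monocytes carried at least 206-fold more Stfa3 and at least 23.3-fold more Csta3, both genes of the stefin family of protease inhibitors. They also carried at least 19.7-fold more Cd34, a surface marker of progenitors (log2 fold change 5.18 ± 0.17 SE, n = 4 per group, adjusted p = 1.06e-21). Chil3, a secreted chitinase-like protein of myeloid cells, was 181-fold lower in fetal liver (log2 fold change -7.50 ± 0.14), and H2-Aa, an MHC class II chain, was at least 7.94-fold lower. Pparg, the transcription factor that directs alveolar macrophage differentiation, was 5.09-fold higher in fetal liver (log2 fold change 2.35 ± 0.14, adjusted p = 2.18e-14). Cx3cr1, a chemokine receptor, was lower by a log2 fold change of -2.65 ± 0.21.

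Cell cycle genes were higher in fetal liver monocytes in 26 of 29 measured members (28 adjusted over the list alone), among them Uhrf1 (log2 fold change 2.07), Mcm5 (1.35) and Mcm7 (1.26). The set test adjusted p was 0.0132 with an estimated correlation. All 20 interferon response genes were lower (20 adjusted over the list alone; adjusted p = 0.00552 with an estimated correlation), among them Usp18 (-2.44) and Mx2 (-1.95). Of 12 genes of MHC class II presentation, 7 were lower and 1 was higher (7 and 2 adjusted over the list alone; adjusted p = 0.0456 with an estimated correlation). H2-Ab1 differed by -3.47. Of 9 genes of fetal growth, 5 were higher and none lower (5 adjusted over the list alone; adjusted p = 0.00668 with an estimated correlation). Igf2bp3, an RNA-binding protein of fetal tissue, differed by 3.18 ± 0.17, and Igf2bp1 by 1.85. Classical monocyte markers were lower in 11 of 19 members and higher in 1 (11 and 1 adjusted over the list alone; adjusted p = 0.0231 with an estimated correlation). Ms4a4c was among the lower ones (-1.84), and Thbs1 was the higher one (3.74). Markers of other cells moved beside these groups. Neutrophil markers were higher in 6 of 12 members and lower in 2 (6 and 2 adjusted over the list alone), with Stfa3, Stfa2 and the granule protease Prtn3 (1.75) in the lead, but the set test was lost at adjusted p = 0.074 with an estimated correlation. Progenitor markers were higher in 5 of 10 members and lower in 1 (5 and 1 adjusted over the list alone; adjusted p = 0.137 with an estimated correlation), with Mpo at 2.20. Dendritic cell markers were lower in 3 of 7 members (3 adjusted over the list alone; adjusted p = 0.0231 with an estimated correlation), with Kmo at -1.30. In all, 1292 genes were higher and 1098 lower in fetal liver monocytes by limma, with 341 and 301 of them changed at least 2-fold.

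Yolk sac macrophages were compared with both monocyte populations. Against bone marrow monocytes they carried at least 246-fold more Dab2, an endocytic adaptor, at least 78-fold more C1qb, a chain of complement C1q, at least 105-fold more Lyve1 and 134-fold more Mrc1, both scavenger-type receptors. The chemokine genes Pf4 and Cxcl2 were at least 240-fold and at least 168-fold higher. The monocyte genes S100a8 (at least 259-fold), Chil3 (at least 198-fold), S100a9 (at least 209-fold) and Ifitm6 (at least 104-fold) were lower. Ccr2, the receptor that guides monocyte exit from the marrow, was lower by a log2 fold change of -7.45 ± 0.22 (n = 4 per group, adjusted p = 2.25e-24). Timd4, a receptor for dying cells on tissue macrophages, was higher by 2.48 ± 0.15. Against fetal liver monocytes, Mrc1 was at least 141-fold higher and S100a8 at least 334-fold lower. Csf2rb was lower than in either monocyte, by -1.39 ± 0.19 against bone marrow and -2.12 ± 0.19 against fetal liver.

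Tissue and fetal macrophage markers were higher in yolk sac macrophages in 22 of 23 members in either comparison (22 adjusted over the list alone in each; adjusted p = 2.27e-10 against bone marrow and 8.60e-12 against fetal liver with an estimated correlation). C1qa (log2 fold change 6.20 and 6.15) and Stab1 (5.75 and 5.77) were among them. Classical monocyte markers were lower in 18 of 19 members against bone marrow (18 adjusted over the list alone; adjusted p = 3.70e-08 with an estimated correlation) and in 17 against fetal liver (17 lower and 1 higher adjusted over the list alone). Mgst1, a detoxifying enzyme of the membrane, differed by -7.69 and -6.63. Inflammatory mediators were higher in 16 of 21 members and lower in 2 against bone marrow (16 and 2 adjusted over the list alone; adjusted p = 0.00351 with an estimated correlation) and in 16 and 2 against fetal liver (16 and 3 adjusted over the list alone). The chemokine Ccl4 differed by 5.84 and the cytokine Il1a by 5.34 against bone marrow. Early response genes were higher in 16 of 18 members and lower in 1 against bone marrow (16 and 1 adjusted over the list alone; adjusted p = 0.00402 with an estimated correlation), with Egr1 at 6.79 and Egr2 at 6.01. Yolk sacs and fetal livers were digested with collagenase, while bones were crushed and alveolar macrophages were washed out. Whether this handling affected the early response genes was not tested. Interferon response genes were higher in 17 of 20 members and lower in 1 against fetal liver (17 and 1 adjusted over the list alone), but the set test was lost at adjusted p = 0.0594 with an estimated correlation. Cell cycle genes were higher in 20 of 29 members against bone marrow (23 adjusted over the list alone; adjusted p = 0.217 with an estimated correlation), with Uhrf1 at 2.45.

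Markers of other cells also differed. Erythroid genes were higher in yolk sac macrophages in 4 of 6 members against bone marrow (4 adjusted over the list alone; adjusted p = 0.0186 with an estimated correlation). They were led by the embryonic globins Hbb-y (log2 fold change 6.94 ± 0.18), Hba-x (4.17 ± 0.16) and Hbb-bh1 (3.26 ± 0.19). Genes of yolk sac endoderm and liver were higher in 4 of 7 members (4 adjusted over the list alone; adjusted p = 0.136 with an estimated correlation), with Afp, the fetal serum protein, at 1.79. Neutrophil markers were lower in 11 of 12 members and higher in 1 against fetal liver (11 and 1 adjusted over the list alone; adjusted p = 0.00153 with an estimated correlation), with Prtn3 at -6.42. By limma 2948 genes were higher and 2218 lower in yolk sac macrophages than in bone marrow monocytes, and 2283 were higher and 1774 lower than in fetal liver monocytes.

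Each precursor was compared with its own descendants to show how its expression changed over 6 weeks in the lung. From bone marrow monocyte to BM-derived macrophage, Fabp1, a fatty acid carrier, rose at least 180-fold, Atp6v0d2, a subunit of the lysosomal proton pump, at least 212-fold, and Plet1, a surface protein, 236-fold. Car4, a membrane carbonic anhydrase of alveolar macrophages, rose by 7.58 ± 0.15 on the log2 scale (n = 4 per group, adjusted p = 3.52e-29). Itgax, the integrin CD11c, rose by 6.27 ± 0.19, Fabp4 by 5.13 ± 0.21, Pparg by 4.73 ± 0.14 and Siglecf, a sialic acid receptor, by 2.95 ± 0.19. S100a9 fell at least 209-fold, Plac8 at least 204-fold and Ifitm6 at least 104-fold. The receptors Ccr2 and Cx3cr1 changed by -5.78 ± 0.22 and -4.63 ± 0.21. Csf2rb rose by 1.58 ± 0.19.

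All 26 measured alveolar macrophage markers rose in the BM-derived cells (26 adjusted over the list alone; adjusted p = 1.37e-09 with an estimated correlation). Of 27 genes of lipid uptake, storage and efflux, 22 rose and 2 fell (23 and 2 adjusted over the list alone; adjusted p = 0.00103 with an estimated correlation). The fatty acid receptor Cd36 (6.09), the lipase Mgll (5.43) and the cholesterol exporter Abcg1 (3.77) rose. Lysosome genes rose in 16 of 24 members and fell in 2 (16 and 2 adjusted over the list alone; adjusted p = 0.0282 with an estimated correlation), with Ctsk at 7.38 and Gpnmb at 6.25. Genes of GM-CSF receptor and signalling rose in 11 of 17 members and fell in 2 (11 and 2 adjusted over the list alone; adjusted p = 0.0282 with an estimated correlation). Their leading members were Pparg, Bhlhe41 (5.32) and Bhlhe40 (4.32). Scavenger and phagocytic receptors rose in 14 of 22 members and fell in 3 (14 and 3 adjusted over the list alone; adjusted p = 0.0022 with an estimated correlation). Mertk, a receptor for dying cells, rose by 5.77, and Itgam changed by -5.58. Classical monocyte markers fell in 15 of 19 members and rose in 1 (15 and 1 adjusted over the list alone; adjusted p = 2.20e-06 with an estimated correlation). Interferon response genes fell in 17 of 20 members (18 adjusted over the list alone), with Usp18 at -2.86, but the set test was lost at adjusted p = 0.0525 with an estimated correlation. Cell cycle genes fell in 17 of 29 members (19 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation), with Aurkb at -1.78. Cholesterol synthesis genes rose in 10 of 17 members (10 adjusted over the list alone; adjusted p = 0.336 with an estimated correlation), with Dhcr7 at 1.82. Neutrophil markers fell in 9 of 12 members and rose in 1 (9 and 1 adjusted over the list alone; adjusted p = 0.0264 with an estimated correlation). In all, 2484 genes rose and 1969 fell by limma.

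From fetal liver monocyte to FL-derived macrophage, Fabp1 rose at least 139-fold, Atp6v0d2 at least 207-fold and Chil3 305-fold. Car4 rose by 7.45 ± 0.15 (n = 4 per group, adjusted p = 4.03e-29), Itgax by 5.96 ± 0.19, Fabp4 by 5.04 ± 0.21, Siglecf by 3.41 ± 0.19 and Pparg by 2.49 ± 0.14. Stfa3 fell at least 206-fold, S100a9 at least 288-fold and Plac8 at least 151-fold. All 26 alveolar macrophage markers rose (26 adjusted over the list alone; adjusted p = 2.66e-09 with an estimated correlation), and all 29 cell cycle genes fell (29 adjusted over the list alone; adjusted p = 0.00574 with an estimated correlation), with Mcm5 at -2.38 and Birc5 at -2.16. Lipid genes rose in 19 of 27 members and fell in 2 (19 and 2 adjusted over the list alone; adjusted p = 0.00222 with an estimated correlation), with Cd36 at 7.36 and Pltp at 4.22. Lysosome genes rose in 20 of 24 members (20 adjusted over the list alone; adjusted p = 0.00566 with an estimated correlation). Cholesterol synthesis genes rose in 13 of 17 members (13 adjusted over the list alone; adjusted p = 0.195 with an estimated correlation), with Msmo1 at 1.83 and Hmgcs1 at 2.11. Fetal growth genes fell in 6 of 9 members (6 adjusted over the list alone; adjusted p = 0.00566 with an estimated correlation), with Arid3a at -2.16 and Igf2bp3 at -1.64. Neutrophil markers fell in 11 of 12 members (12 adjusted over the list alone; adjusted p = 0.00227 with an estimated correlation). By limma 2495 genes rose and 2198 fell.

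From yolk sac macrophage to YS-derived macrophage, Chil3 rose at least 311-fold, Fabp1 at least 186-fold and Car4 at least 122-fold. Itgax rose by 6.24 ± 0.19 (n = 4 per group, adjusted p = 7.17e-24), Fabp4 by 5.25 ± 0.21, Pparg by 3.42 ± 0.14 and Csf2rb by 2.85 ± 0.19. Fcrls fell at least 107-fold, Ms4a6b at least 115-fold and C1qb at least 78-fold. Cx3cr1 changed by -5.26 ± 0.21 and Timd4 by -2.50 ± 0.15. Ccr2 rose by 1.34 ± 0.22. Alveolar macrophage markers rose in 25 of 26 members (25 adjusted over the list alone; adjusted p = 8.53e-09 with an estimated correlation). Tissue and fetal macrophage markers fell in 20 of 23 members and rose in 1 (20 and 1 adjusted over the list alone; adjusted p = 1.35e-08 with an estimated correlation), with Lyve1 at -6.99 and C1qa at -6.17. Early response genes fell in 17 of 18 members and rose in 1 (17 and 1 adjusted over the list alone; adjusted p = 0.00225 with an estimated correlation), with Egr1 at -6.98. Inflammatory mediators fell in 13 of 21 members and rose in 4 (13 and 5 adjusted over the list alone; adjusted p = 0.0287 with an estimated correlation). Ccl4 changed by -5.56 and Il1rn, which blocks interleukin 1, rose by 4.05. Lipid genes rose in 23 of 27 members and fell in 2 (23 and 2 adjusted over the list alone; adjusted p = 0.00225 with an estimated correlation). Cholesterol synthesis genes rose in 16 of 17 members (16 adjusted over the list alone; adjusted p = 0.116 with an estimated correlation), and cell cycle genes fell in 28 of 29 (28 adjusted over the list alone; adjusted p = 0.0287 with an estimated correlation). MHC class II genes rose in 8 of 12 members and fell in 1 (8 and 2 adjusted over the list alone; adjusted p = 0.219 with an estimated correlation), with H2-DMa at 5.12 and Cd86 at -4.57. The embryonic globin Hbb-y changed by -6.90 ± 0.18, and 4 of 6 erythroid genes fell (4 adjusted over the list alone; adjusted p = 0.0223 with an estimated correlation). By limma 2405 genes rose and 2845 fell.

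**Figure D2:**
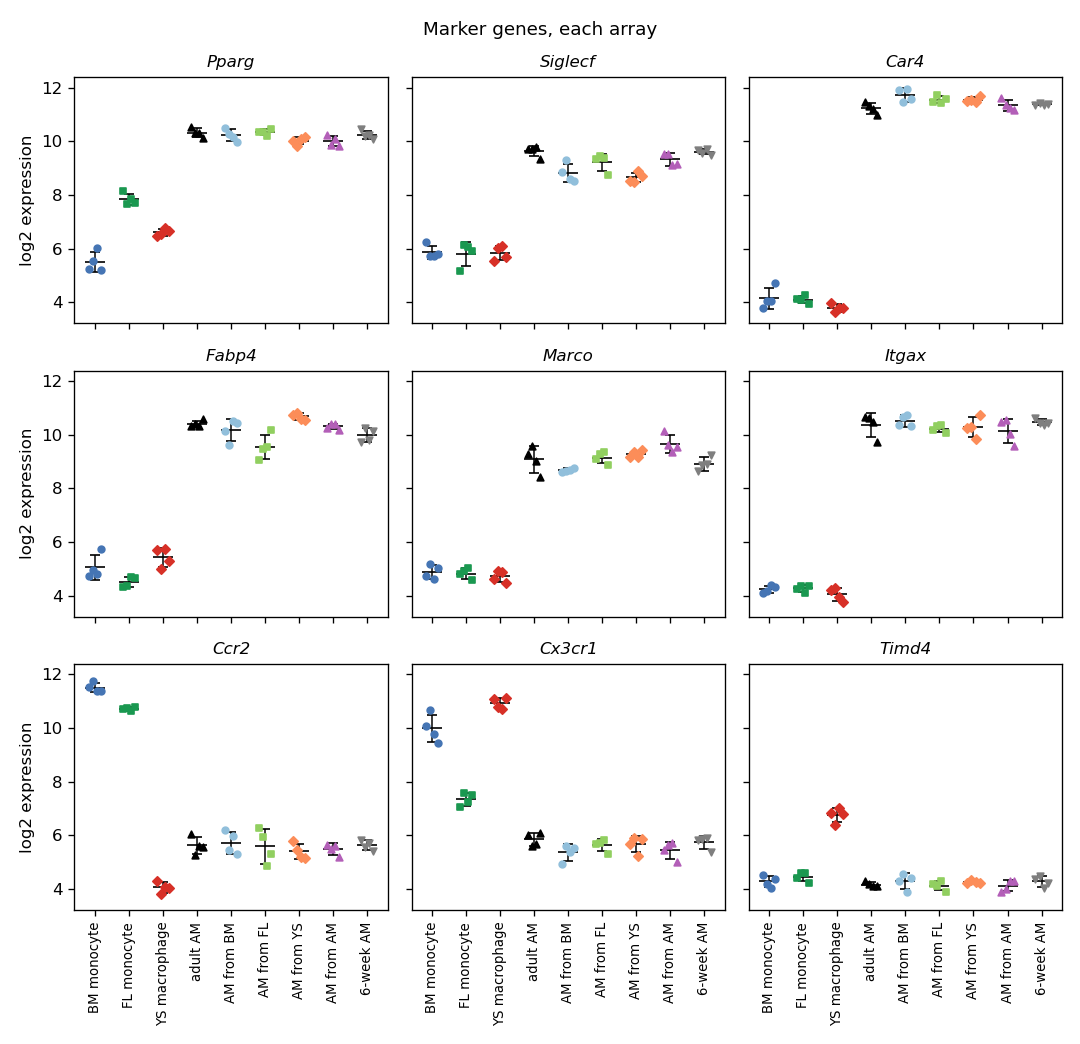
Log2 expression of 9 marker genes in the 9 groups, with 1 point per array and lines for the mean ± SD of 4 arrays. Pparg lies near 10 in all 6 groups of alveolar macrophages, between 10.01 in AM-derived and 10.34 in FL-derived macrophages, and at 5.50 in bone marrow monocytes.

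Several genes of the fixed panel reached a similar level in all 6 groups of alveolar macrophages. The group means of Car4 lay between 11.24 ± 0.21 (SD, n = 4) in adult and 11.73 ± 0.25 in BM-derived macrophages, against 4.15 ± 0.41 in bone marrow monocytes. Itgax lay between 10.15 ± 0.45 in AM-derived macrophages and 10.52 ± 0.21 in BM-derived macrophages, against 4.05 ± 0.23 in yolk sac macrophages. Csf2rb lay between 9.59 ± 0.45 and 9.85 ± 0.10 in the 6 groups. Ccr2 lay between 5.40 ± 0.30 and 5.72 ± 0.42, against 11.51 ± 0.17 in bone marrow and 10.71 ± 0.06 in fetal liver monocytes. The root mean square log2 distance from the controls over all genes tested was 0.969 ± 0.0107 for bone marrow monocytes, 1.00 ± 0.0139 for fetal liver monocytes and 1.10 ± 0.015 for yolk sac macrophages. It was 0.353 ± 0.0258 for BM-derived, 0.346 ± 0.0251 for FL-derived, 0.367 ± 0.0133 for YS-derived and 0.357 ± 0.032 for AM-derived macrophages. The controls themselves, each set against the others of their group, lay at 0.295 ± 0.0144, and untreated adult macrophages at 0.319 ± 0.0649. The distance of the other 3 derived groups differed from that of AM-derived macrophages by less than the spread between samples. Exact two-sided permutation p values were 0.857, 0.571 and 0.571 for BM-, FL- and YS-derived cells, each 0.857 after adjustment over the 3 comparisons (n = 4 per group). The smallest p value that 4 against 4 allows is 0.0286.

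**Figure D3:**
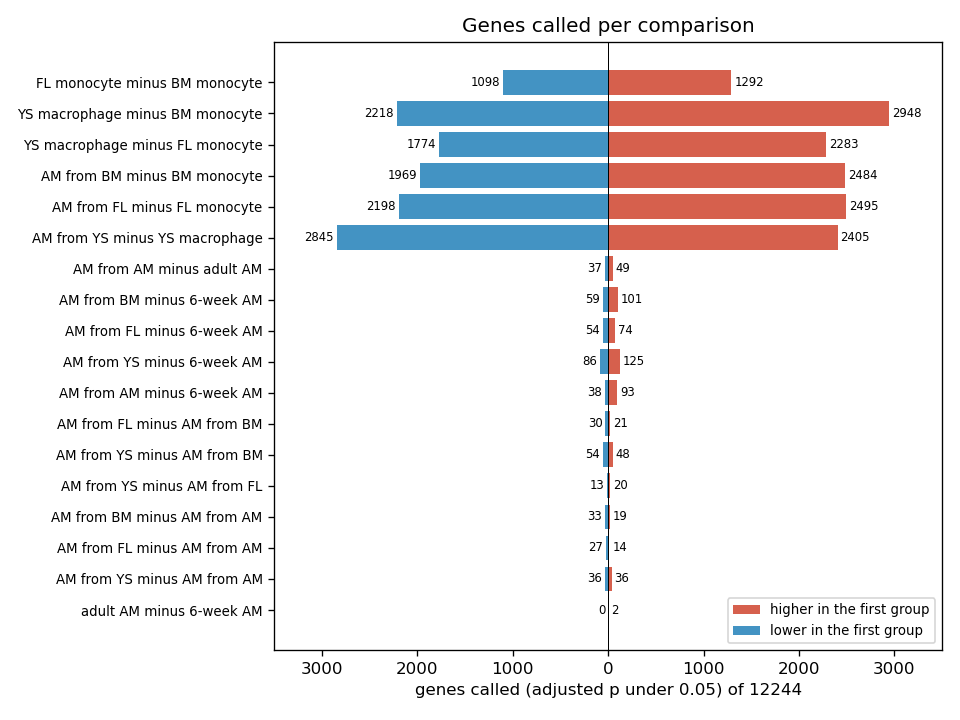
Number of genes called higher and lower in each comparison by limma, as bars to the right and left of 0 on a linear axis (number of genes of 12244 tested). Comparisons among precursors or between a precursor and its descendants called between 2390 and 5250 genes, and those among alveolar macrophage groups between 2 and 211.

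Pairs of origins were compared before and after transfer to show how much of the difference between precursors remained. Of 2390 genes that differed between fetal liver and bone marrow monocytes, 17 still differed in the same direction between FL- and BM-derived macrophages (0.711%), where independent lists would share 4.91, and 1 differed in the opposite direction. The 17 made up 33.3% of the 51 differences after transfer. The genes kept included the MHC class II genes H2-Aa, H2-Ab1 and Cd74, the apolipoprotein gene Apoc1, the ribosomal protein gene Rps4l, and Igf2bp3. Of 5166 genes that differed between yolk sac macrophages and bone marrow monocytes, 57 still differed alike (1.10%, 21.3 for independent lists), and 7 differed in the opposite direction. The genes kept were 55.9% of the differences after transfer. Of 4057 genes for yolk sac against fetal liver, 23 still differed alike (0.567%, 5.61 for independent lists), and 2 in the opposite direction, with 69.7% of the differences after transfer among those kept. P-values were adjusted within each contrast, which set a stricter bar after transfer, where few genes were called. The shares of precursor differences that were kept can therefore be too low. All contrasts used 1 estimate of the spread per gene, which favours the same genes before and after transfer. The counts given for independent lists can therefore be too low as well. The genes named from the overlap were picked after their values were seen. Napsa, an aspartic protease gene, was lower in yolk sac macrophages than in fetal liver monocytes by -6.08, and lower by -2.27 ± 0.25 in their descendants. Igf2bp3 was higher in fetal liver than in bone marrow monocytes by 3.18 and higher by 1.27 ± 0.17 in FL- than in BM-derived macrophages. The change over transfer itself differed between fetal liver and bone marrow origin for 1217 genes by limma, 522 higher and 695 lower. It differed for 3751 genes between yolk sac and bone marrow and for 2808 between yolk sac and fetal liver. Chil3 rose 179-fold more from fetal liver than from bone marrow monocytes, and Pparg rose less by a log2 difference of -2.24 ± 0.20 (n = 4 per group, adjusted p = 9.45e-10). Interferon response genes changed upward in 16 of 20 members in that contrast (20 adjusted over the list alone; adjusted p = 0.0158 with an estimated correlation). Cell cycle genes changed downward in 19 of 29 (25 adjusted over the list alone; adjusted p = 0.0212 with an estimated correlation).

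Transferred alveolar macrophages were compared with those of untreated adults, the population they were taken from, to show what passage through the recipient lung changed. Ddah1, an enzyme that degrades methylated arginine, rose 12.1-fold (log2 fold change 3.59 ± 0.55, n = 4 per group, adjusted p = 0.000204). Mmp12, the macrophage elastase, rose 6.82-fold, Scd1, a fatty acid desaturase, 5.06-fold and Mfge8, a bridge to dying cells, 4.96-fold. Fn1, fibronectin, changed by -3.38 ± 0.40 (adjusted p = 2.90e-06), Emb by -2.73 ± 0.43 and Inka1 by -1.76 ± 0.25. None of the 10 panel genes was called, with Marco at 0.58 ± 0.18 and Pparg at -0.31 ± 0.14. None of the 17 cholesterol synthesis genes was called (4 lower adjusted over the list alone). Their set test was lost at adjusted p = 0.539 with an estimated correlation, and Cyp51 lay at -0.73. By limma 49 genes rose and 37 fell, and 45 were called when only these groups entered the fit.

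Each derived group was compared with the controls of matched age. Scd1 was higher in all 4 derived groups, by 3.22 ± 0.37 in BM-derived, 3.17 ± 0.37 in FL-derived, 3.57 ± 0.37 in YS-derived and 4.00 ± 0.37 in AM-derived macrophages (n = 4 per group, adjusted p = 5.76e-07, 2.52e-06, 5.47e-08 and 3.58e-08). Awat1, a wax ester synthase, was at least 9.26-fold higher in BM-derived and at least 8.13-fold higher in FL-derived cells. Mfge8 was 5.82-fold, 6.02-fold, 7.42-fold and 4.81-fold higher, in the same order of groups. Ddah1 was 62.0-fold higher in YS-derived and 13.8-fold higher in AM-derived macrophages. Apoc1 was lower in BM-derived macrophages by -4.09 ± 0.43, Emb by -3.45 ± 0.43 and Wfdc10 by -2.95 ± 0.27. Cldn1, a tight junction protein, was lower in YS-derived macrophages by -3.34 ± 0.34, and the splicing regulator Mbnl3 by -2.82 ± 0.28. Fn1 was lower in AM-derived macrophages by -3.72 ± 0.40. Siglecf was lower in YS-derived macrophages by -0.96 ± 0.19 (adjusted p = 0.00183). In BM-derived macrophages it was lower by -0.80 ± 0.19 (adjusted p = 0.0185), a call that was lost without BM-derived array 3 (adjusted p = 0.10), BM-derived array 4 (0.112), control array 1 (0.0675) or control array 3 (0.0732).

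Most alveolar macrophage markers were not called against the controls. Of 26 members, 2 rose and 1 fell in BM-derived and in FL-derived cells, 1 rose and 4 fell in YS-derived cells, and 2 rose in AM-derived cells. Adjusted over the list alone, 2 rose and 1 fell in BM-derived, 2 and 2 in FL-derived, 3 and 4 in YS-derived, and 3 and 0 in AM-derived cells. None of these set tests was called (adjusted p = 0.955, 0.529, 0.847 and 0.938), and the list's median and mean differed in sign in BM-derived (0.04 and -0.002), YS-derived (0.01 and -0.09) and AM-derived cells (-0.005 and 0.02). Cdh1, E-cadherin, was higher in all 4 derived groups, by 0.96 in BM-, 0.74 in FL-, 1.02 in YS- and 0.78 in AM-derived cells (each ± 0.19), and in AM-derived against adult macrophages by 0.84. The calls for FL- and AM-derived cells against controls were lost without any of several single arrays (adjusted p up to 0.254 and 0.176), as was that against adult macrophages (up to 0.125), and all 3 were lost with only the groups compared in the fit (0.214, 0.0627 and 0.137). Epcam was lower in YS-derived (-2.02 ± 0.36) and FL-derived cells (-1.43 ± 0.36), the latter lost without single arrays (adjusted p up to 0.268) or with only the groups compared (0.27). Both genes also mark lung epithelium, and none of its 10 markers other than Cdh1 and Epcam was called against controls. MHC class II genes parted the derived groups. In AM-derived macrophages 5 of 12 members rose (5 adjusted over the list alone, set test adjusted p = 0.84 with an estimated correlation), among them H2-Eb1 (2.27 ± 0.41) and Cd74 (2.06 ± 0.39). Against adult macrophages, the population these cells were taken from, neither Cd74 nor any H2 gene was called. H2-Ab1 was itself higher by 1.32 in adult than in 6-week macrophages, without a call. In BM-derived macrophages 1 rose, Cd74 at 1.72 ± 0.39 (5 adjusted over the list alone; adjusted p = 0.502 with an estimated correlation), a call lost without BM-derived array 3 (adjusted p = 0.0803), BM-derived array 4 (0.0591) or control array 3 (0.125), or with only these groups in the fit (0.124). In FL-derived macrophages 3 fell, with H2-Ab1 at -2.26 ± 0.41 and H2-Aa at -2.44 ± 0.45 (5 lower and 1 higher adjusted over the list alone; adjusted p = 0.211 with an estimated correlation). Both calls were lost when only the groups compared entered the fit (adjusted p = 0.109 and 0.124). In YS-derived macrophages 1 fell, Ifi30 at -0.50 ± 0.13 (4 lower and 1 higher adjusted over the list alone; adjusted p = 0.29 with an estimated correlation), a call lost without any single one of the 8 arrays except control array 3 (adjusted p from 0.0503 to 0.155). Interferon response genes rose in 4 of 20 members in YS-derived cells (8 adjusted over the list alone; adjusted p = 0.139 with an estimated correlation) and in 3 in BM-derived cells (7 adjusted over the list alone; adjusted p = 0.178 with an estimated correlation), with Oas1a at 1.25 and 1.36. Lipid genes rose in 3 of 27 members and fell in 1 in YS-derived cells (5 and 1 adjusted over the list alone; adjusted p = 0.426 with an estimated correlation), with Scd1 in the lead.

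By limma 101 genes were higher and 59 lower than controls in BM-derived, 74 and 54 in FL-derived, 125 and 86 in YS-derived, and 93 and 38 in AM-derived macrophages. For FL-derived cells 74 genes in total were called when only these groups entered the fit. A set of 47 genes, 35 higher and 12 lower, was called alike in the BM-, FL- and AM-derived comparisons, and 45 of them also in the YS-derived comparison. These comparisons share their control arrays. Simulated groups without any change shared 0 calls in each of 100 simulations, and independent lists of these sizes would share 0.00544 genes. The simulation held no shift of the control arrays as a whole, and independent lists leave out the shared controls. Neither value can tell an effect of transfer from control arrays that stand apart. The covariance of the fold changes was 0.041 for BM- with FL-derived, 0.0418 for BM- with AM-derived and 0.0369 for FL- with AM-derived cells. Simulated values without effects were 0.0179, 0.018 and 0.0179, and values with the controls split between the comparisons were 0.0248, 0.0256 and 0.0207. When only the groups compared entered each fit, 28 genes were shared. The control arrays differed in sex-linked genes, and whether a sample came from 1 animal or from a pool is not given in the sources used here. Xist, expressed from the inactive X chromosome, read 4.31, 8.99, 9.24 and 3.73 in control arrays 1 to 4, and the Y-linked gene Eif2s3y read 7.88, 2.65, 2.85 and 7.87. None of the 4 sex-linked genes was called in any of the 4 comparisons with controls. The wide spread of such genes between control arrays makes a call unlikely, so this does not show that sex was balanced.

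**Figure D4:**
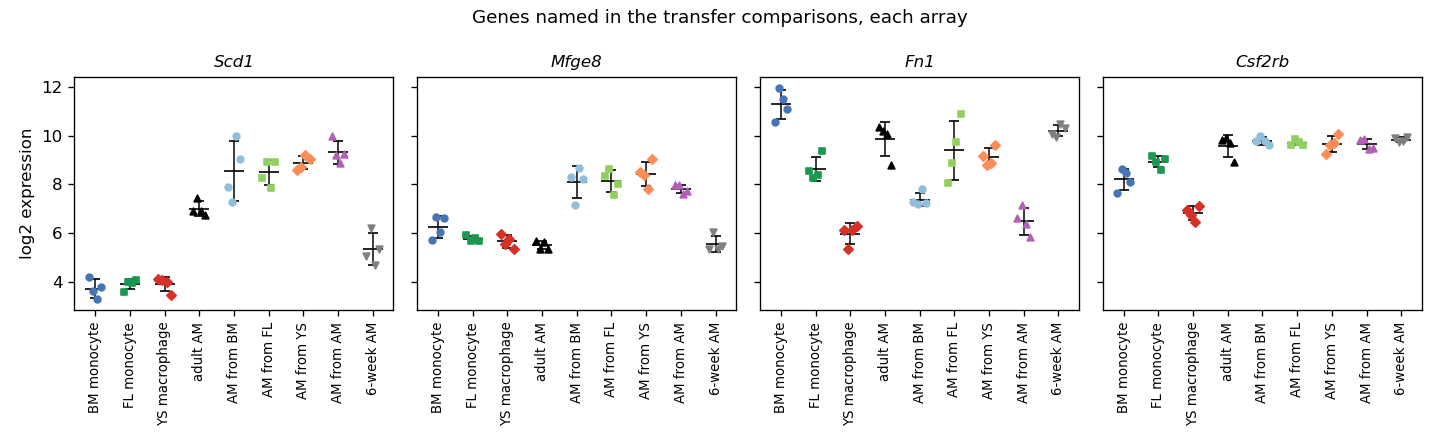
Log2 expression of Scd1, Mfge8, Fn1 and Csf2rb in the 9 groups, with 1 point per array and lines for the mean ± SD of 4 arrays. Scd1 has a mean of 5.33 in controls and 6.99 in adult macrophages, against 8.49 to 9.33 in the 4 derived groups.

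Untreated alveolar macrophages of adults and of 6-week-old mice were compared as a measure of how far wild-type groups differ. Clec1b, a C-type lectin, was higher in adults by 1.83 ± 0.28 (n = 4 per group, limma adjusted p = 0.00277), and Tmem9 by 1.00 ± 0.18 (adjusted p = 0.0141). No other gene was called, and 499 genes had an unadjusted p under 0.05. The call of Tmem9 was lost without adult array 4 (adjusted p = 0.227), control array 3 (0.0951) or control array 4 (0.238), and with only these groups in the fit 0 genes were called. None of the 12 MHC class II genes was called (4 higher adjusted over the list alone; adjusted p = 0.375 with an estimated correlation), with Cd74 at 1.42 ± 0.39. The set test of the 4 sex-linked genes was lost at adjusted p = 0.0899 with an estimated correlation, with none called adjusted over the list alone.

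The derived groups were compared with each other to show what remained of the origin in the same tissue. Of 12 MHC class II genes, 4 were lower in the FL- and YS-derived than in the BM- and AM-derived groups, and none was called between FL- and YS-derived or between BM- and AM-derived macrophages. H2-Aa was lower by -3.80 ± 0.45 in FL- than in BM-derived macrophages, H2-Ab1 by -3.74 ± 0.41, Cd74, the class II invariant chain, by -3.67 ± 0.39, and H2-Eb1 by -2.62 ± 0.41 (n = 4 per group, adjusted p = 2.62e-06, 5.13e-07, 4.51e-07 and 0.000347). The call of H2-Eb1 was lost when only the groups compared entered the fit, here (adjusted p = 0.0764) and for YS- against BM-derived cells (0.0505). Against AM-derived macrophages the same 4 genes were lower in FL-derived cells by -4.39, -4.13, -4.01 and -3.40. In YS-derived cells they were lower by -2.79, -2.93, -2.71 and -2.31 against BM-derived and by -3.38, -3.32, -3.05 and -3.09 against AM-derived macrophages. The mean log2 level of H2-Ab1 was 10.23 ± 0.57 (SD) in BM-derived, 10.62 ± 0.27 in AM-derived, 6.48 ± 0.93 in FL-derived and 7.29 ± 0.75 in YS-derived macrophages, with 8.74 ± 0.89 in controls. Before transfer it was 7.41 ± 0.11 in bone marrow monocytes, 3.94 ± 0.14 in fetal liver monocytes and 4.21 ± 0.48 in yolk sac macrophages. In each of these 4 comparisons 4 of the 12 class II genes were lower. Adjusted over the list alone, 6 were lower and 1 higher for FL- against BM-derived, 6 lower for YS- against BM-derived, 5 lower and 1 higher for FL- against AM-derived, and 5 lower for YS- against AM-derived cells. The set test held at adjusted p = 0.00544, 0.0219, 0.0176 and 0.0127 with an estimated correlation, in the same order.

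Apoc1, an apolipoprotein gene, was at least 22.4-fold higher in FL-derived and at least 21.1-fold higher in YS-derived than in BM-derived macrophages (log2 fold change 4.66 ± 0.43 and 4.57 ± 0.43, n = 4 per group, adjusted p = 3.13e-08 and 1.29e-08). It was at least 22.4-fold lower in BM- than in AM-derived macrophages. Its mean level was 4.46 ± 0.54 (SD) in BM-derived macrophages and 8.29 ± 0.54 in the monocytes they came from, against 9.11 ± 1.15 in FL-derived and 8.54 ± 0.45 in controls. Wfdc10 was lower by -3.34 ± 0.27 in BM- than in AM-derived macrophages, and Xlr by -3.00 ± 0.31. Lrg1 (6.21-fold), Hnmt (at least 2.32-fold), which degrades histamine, and Arhgap15 (at least 2.2-fold) were higher in BM- than in AM-derived macrophages. Marco, a scavenger receptor, was lower by -0.99 ± 0.18 in the same comparison (adjusted p = 0.00315). Scgb1a1, a marker of club cells of the lung epithelium, was also lower there by -1.89 ± 0.44 (adjusted p = 0.0414), a call lost in most alternative fits (adjusted p up to 0.25, without BM-derived array 2). By limma 21 genes were higher and 30 lower in FL- than in BM-derived cells. In BM- against AM-derived cells 19 were higher and 33 lower. That total of 52 fell to 29 without BM-derived array 1 and to 30 without AM-derived array 3, and to 32 when only the groups compared entered the fit.

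YS-derived macrophages differed from both monocyte-derived groups in a set of genes. Ddah1 was 16.4-fold higher than in BM-derived and 11.8-fold higher than in FL-derived cells, although the second call was lost when only the groups compared entered the fit (adjusted p = 0.353). Cldn1 was lower by -3.11 ± 0.34 and -3.06 ± 0.34, and Mbnl3 by -2.97 ± 0.28 and -2.66 ± 0.28 (n = 4 per group, adjusted p = 1.29e-08 and 7.48e-07 for Mbnl3). Napsa was lower by -2.27 ± 0.25 than in FL-derived cells, with adjusted p = 0.0507 when only the groups compared entered the fit. The growth hormone receptor gene Ghr was at least 2.38-fold and the complement gene C2 at least 2.71-fold higher in YS- than in AM-derived macrophages. Fn1 was 6.22-fold higher in that comparison. Fn1 was also 7.56-fold higher in FL- than in AM-derived macrophages, with adjusted p = 0.0774 when only the groups compared entered the fit. Igf2bp3 was higher by 1.38 ± 0.17 in FL- and by 1.58 ± 0.17 in YS- than in AM-derived macrophages. Fabp4 was higher in YS- than in FL-derived cells by 1.13 ± 0.21 (adjusted p = 0.00495), a call that was lost without FL-derived array 1 (adjusted p = 0.0503) or with only these groups in the fit (0.127). Csf2rb was not called in any of the 6 comparisons between derived groups, and neither were Pparg, Car4, Itgax and Siglecf. By limma 48 genes were higher and 54 lower in YS- than in BM-derived cells, 20 and 13 in YS- against FL-derived, 14 and 27 in FL- against AM-derived, and 36 and 36 in YS- against AM-derived cells. With only the groups compared in the fit, the totals were 13 for FL- against BM-derived, 63 for YS- against BM-derived, 9 for YS- against FL-derived and 15 for FL- against AM-derived cells. Without 3 arrays that stood apart the last was 24.

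**Figure D5:**
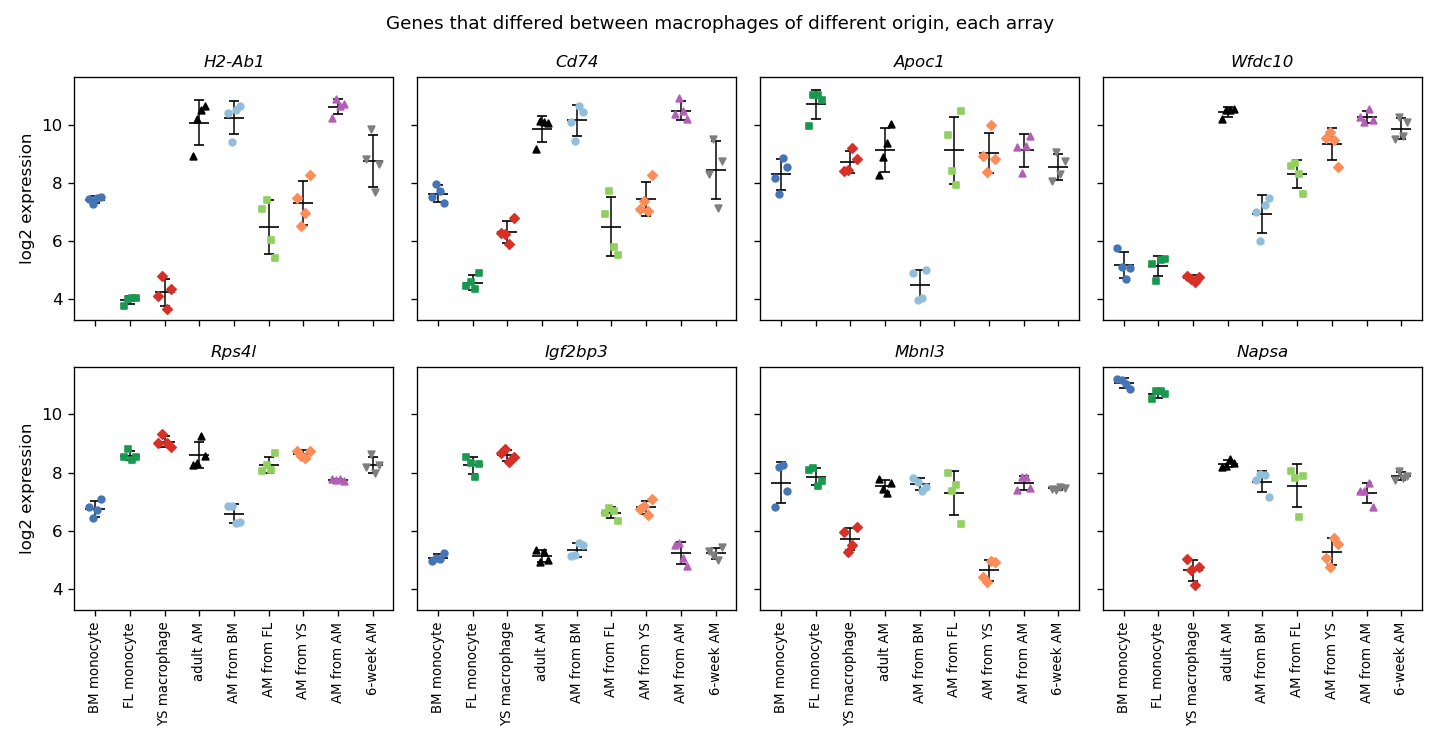
Log2 expression of 8 genes that differed between derived groups, in the 9 groups, with 1 point per array and lines for the mean ± SD of 4 arrays. H2-Ab1 has a mean of 6.48 in FL-derived and 10.23 in BM-derived macrophages, and Apoc1 a mean of 4.46 in BM-derived and 9.11 in FL-derived macrophages.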

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

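Apart from the splits of the samples, the tests of explanations in this part were chosen only after the results they bear on had been seen, and they include the contrast of adult with embryonic donors.

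In the derived macrophages, H2-Aa (log2 difference 3.59 ± 0.32), H2-Ab1 (3.53 ± 0.29), Cd74 (3.36 ± 0.28) and H2-Eb1 (2.86 ± 0.29) were higher in the BM- and AM-derived groups, from adult donors, than in the FL- and YS-derived groups, from embryonic donors, where limma called 45 genes higher and 35 lower. A stronger interferon response that raises the 20 listed interferon genes together is argued against in the adult-donor groups, since they differed by a median of -0.047. A response that acts on other genes is not covered by this list and stays open. Dendritic or B cells among the sorted cells stay open: 14 genes other than these 4 were at least 2-fold higher, while the 10 dendritic and B cell markers differed by -0.16 to 0.58, led in level by Bst2 (8.26 in controls), and a bound that would have excluded them was withdrawn after its value was seen because a small admixture could stay under it. Age of the donor cells also stays open, since H2-Ab1 was higher by 1.32 in adult than in 6-week macrophages without a call. A lasting difference between adult and embryonic origin, which the design names, was not separated from these and remains a hypothesis.

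Apoc1, Lyplal1, Mcts2, Rps4l, Wfdc10 and Wwtr1 were lower in BM-derived macrophages than in each of the other 3 derived groups and in controls, although at least 1 of these calls was lost without a single array for Lyplal1 (adjusted p up to 0.158, without BM-derived array 3), Mcts2 (up to 0.266, without BM-derived array 4) and Wfdc10 (0.0608, without BM-derived array 2), and with only the groups compared in the fit for the same 3 genes (up to 0.0654, 0.366 and 0.28). Between control arrays with high and low Xist these 6 genes differed by a median of 0.203 and at most 0.538. Between BM-derived cells and controls they differed by at least 0.828, a value that their selection can enlarge. The sex composition of the samples is argued against for Apoc1 (0.268 against -4.085), Lyplal1 (0.064 against -0.828), Rps4l (0.073 against -1.702) and Wfdc10 (0.139 against -2.945). It stays open for Mcts2 (-0.469 against -1.255) and Wwtr1 (-0.538 against -1.077), where the margin is smaller and 2 arrays against 2 leave it uncertain. A donor strain variant under the probes would shift all arrays of bone marrow origin alike. As the only source it is argued against for 1 gene, Apoc1. The deficit of Apoc1 against fetal liver origin grew over transfer from 2.41 to 4.66 (limma interaction adjusted p = 0.0134). Such a variant stays open for the part of that deficit present before transfer, and for the other 5 genes. A difference already present between the donor monocytes may contribute for the 4 of the 6 genes that were lower in bone marrow than in fetal liver monocytes, but for Apoc1, 1 of the 4, it does not account for the growth of the deficit. No such difference was measured for Wfdc10 (-0.02) and Wwtr1 (-0.04), whose deficit grew over transfer (interaction 1.38 and 1.67, the former lost with only the groups compared at adjusted p = 0.0607), but their levels of 5.15 and 5.46 in bone marrow monocytes lie near the table median of 4.62, where a difference can be hidden.

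A set of 67 genes was called alike in BM-, FL- and YS-derived macrophages against the 6-week controls. That the control arrays stand apart from other wild-type arrays is argued against for 32 of them. These were called with the same sign between AM-derived and adult macrophages, a comparison that shares no array with the others. Of the 67 genes, 62 had the same sign there and none was called with the opposite sign. Independent lists would share 0.471 calls of either sign. That value can be too low, since 1 estimate of the spread per gene served all comparisons. For the other 35 genes, control arrays that stand apart stay open. Arrays of transferred and untransferred cells may have been processed apart, which cannot be told apart from transfer here because no batch is given, and the 2 genes called between the untransferred groups do not bear on it, since those groups may have been processed together. A response to the lipid load of the recipient lung was likewise left open, with an adjusted p of 0.502 with an estimated correlation for the lipid list in BM-derived cells.

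The change over transfer differed between origins, by the interaction contrasts, for 1217 genes (fetal liver against bone marrow), 3751 (yolk sac against bone marrow) and 2808 (yolk sac against fetal liver). In 100 splits drawn with origins exchanged among donor and among derived arrays, 4 gave as many for the smallest of these counts, with 1435 as the highest other. For the others 1 split, the real one, did, with 2 and 2658 as the highest others. Since donor labels were exchanged too, such splits also remove the differences between donors. They cannot show whether the interaction itself lies beyond chance, and no conclusion is drawn from them.

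For comparisons of 4 against 4 there are 35 splits of the 8 arrays. The real split gave the most calls of all 35 for fetal liver against bone marrow monocytes (2390, highest other 235). It did so for yolk sac macrophages against bone marrow (5166, 642) and fetal liver monocytes (4057, 487). It also did for the change from bone marrow (4453, 760), fetal liver (4693, 381), yolk sac (5250, 20) and adult alveolar cells (86, 55). The split with 55 calls set arrays 1 and 2 of AM-derived and of adult macrophages against the other arrays of both groups. It groups samples across transfer, so a difference other than transfer gave these 55 calls. The cause of that difference was not tested. The real split again gave the most calls for BM-, FL-, YS- and AM-derived cells against controls (160 and 23, 128 and 14, 211 and 1, 131 and 2). The same held for FL- against BM-derived (51, 5), YS- against BM-derived (102, 7), YS- against FL-derived (33, 7), BM- against AM-derived (52, 2), FL- against AM-derived (41, 2) and YS- against AM-derived cells (72, 2). For adult against 6-week macrophages it did not, as 3 of 35 splits gave at least the 2 genes called, with 5 as the highest other. A share of 1 in 35 is the smallest that these splits allow, and it was not adjusted over the 18 comparisons. The splits bear on the number of calls, so chance is not excluded for any single gene.

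Of 207 group values tested, 12 held 1 array far from the other 3, where chance gives 10.3 at 1 in 20. Siglecf read 6.24 in bone marrow monocyte array 1 and 8.75 in FL-derived array 4. Cx3cr1 read 5.37 in control array 4 and Mfge8 6.03 in control array 2. H2-Ab1 read 3.73 and Apoc1 9.95 in fetal liver monocyte array 1. Cd74 read 9.15 and Wfdc10 10.19 in adult array 1. Napsa read 6.46 in FL-derived array 3. Fn1 read 8.81 in adult array 4 and 7.80 in BM-derived array 3. The distance of adult array 4 from the controls was 0.416.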

How the results depend on the processing

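The fit with a sex index and the fit without 3 arrays that stood apart (adult 4, AM-derived 4 and FL-derived 4) were tests chosen only after the results were seen. Of 692 results of named genes, 685 kept their side of the threshold under cyclic loess, 690 under eBayes with trend and robust settings, 692 with the mean of probe sets, 682 without the filter, 687 with the sex index, 669 without the 3 arrays and 606 with only the groups compared, and none changed direction. Over all leave-one-out fits 5978 held, 210 lost and 12 gained a call. A fit with only the groups compared leaves fewer samples to estimate the spread, and it uses the spread of those groups alone. Which of these lowered the counts was not tested. Calls were then 45 for AM-derived against adult, 74 for FL-derived against controls and 13 for FL- against BM-derived cells. They were 63 for YS- against BM-derived, 9 for YS- against FL-derived, 32 for BM- against AM-derived and 15 for FL- against AM-derived cells. Adult against 6-week macrophages gave 0, and 28 transfer calls were shared. Adult against 6-week macrophages gave 4 genes with the sex index and 1 without the 3 arrays, and FL- against AM-derived cells gave 24 without them; the cause was not tested. Of all list tests, 145 were called at the preset and 75 with an estimated correlation. Dim genes near background limit what small folds can show.

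Leaving out 1 array moved 2 counts by over 1.5 times: BM- against AM-derived cells ranged from 29 (without BM-derived 1) to 53, with 30 without AM-derived 3, and adult against 6-week macrophages from 1 (without adult 4, control 3 or control 4) to 5 (without control 2). Differences in profile distance from AM-derived cells, none of them called, ranged from -0.0137 to 0.0118 for BM-derived, from -0.0233 to 0.0045 for FL-derived and from 0.0027 (without AM-derived 1) to 0.0255 (without AM-derived 4) for YS-derived cells, against 0.0099 with all arrays. The first turned sign without BM-derived 2 (0.0071), AM-derived 4 (0.0118) or control 1 (0.0026), the second without AM-derived 4; the cause was not tested. Other counts stayed within 1.5 times, such as 61 to 83 for AM-derived against adult and 32 to 48 for shared transfer calls.

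The replicate numbers were not taken as pairs, as no comparison had every pair of deviations correlated over 0.1. With the replicate block, 51 calls for FL- against BM-derived cells became 56 and 160 for BM-derived against controls became 152, no count moved by over 1.5 times, and 6 of 692 named results lost their call. In 1 comparison, BM-derived cells against bone marrow monocytes, all 4 numbers correlated best with their own (0.03 to 0.13), a hint from the data and not the design. The highest single value, 0.42, was that of number 4 in AM-derived against adult macrophages (0.21, 0.19 and -0.01 for the others), where 2 of 4 correlated best with their own and where array 4 of both groups stood apart.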

Other observations

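The tests of genes outside the rule for named genes in this part were chosen only after their values were seen. The fixed list of lipid genes was called higher than controls in all 4 derived groups at the preset correlation (adjusted p = 0.014, 0.0135, 0.0023 and 0.0314 for BM-, FL-, YS- and AM-derived cells) but in none with an estimated correlation (0.502, 0.58, 0.426 and 0.84), and at most 3 of its 27 members were called higher. Among single genes, Msr1, a scavenger receptor, was higher by 1.92 in BM-derived, 1.51 in FL-derived, 1.87 in YS-derived and 1.22 in AM-derived macrophages (limma adjusted p = 3.50e-09, 7.88e-07, 3.43e-09 and 1.99e-05), and by 1.54 ± 0.16 in AM-derived against adult macrophages (adjusted p = 9.79e-07). Lpcat2, which remodels phospholipids, was higher by 2.11, 1.49, 1.62 and 1.21 in the same order. Trem2, a lipid receptor of macrophages, was higher by 1.04, 0.95, 1.18 and 1.08. Its rise of 0.81 against adult macrophages was lost with only these groups in the fit (adjusted p = 0.11). Hpgd, which degrades prostaglandins, was lower by -1.56, -1.34, -1.36 and -1.59. Its fall of -1.54 against adult macrophages was lost in the same way (adjusted p = 0.0557). The growth factor gene Igf1 was higher by 1.40, 1.37, 1.96 and 1.47, and the first of these calls was lost with only the groups compared in the fit (adjusted p = 0.118).

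Each derived group also had genes that set it apart from the other 3 and from the controls. YS-derived macrophages had 8 lower and 5 higher, BM-derived 6 and 2, FL-derived 2 and 0, and AM-derived 0 and 2. The 5 higher in YS-derived cells were C2, Fsd2, Ghr, Stap2 and the adhesion molecule Nectin3, which had a mean of 5.75 there against 4.36 in controls. Hnmt and Insl6 were the 2 higher in BM-derived cells, Ly86 and Rras2 the 2 lower in FL-derived cells, and Ct55 and Tmem30b the 2 higher in AM-derived cells. In at least 1 of these comparisons a call was lost without a single array for C2 (adjusted p up to 0.0709, without FL-derived array 1), Fsd2 (0.254, without AM-derived array 3), Hnmt (0.198, without YS-derived array 4), Insl6 (0.161, without BM-derived array 3) and Rras2 (0.115, without FL-derived array 1). The same held for 5 of the 8 lower in YS-derived cells: Agap2 (0.175, without YS-derived array 2), Plcb1 (0.136, without FL-derived array 3), Cd48 (0.109, without YS-derived array 2), Fcgr2b (0.0716, without YS-derived array 2) and 4930523C07Rik (0.0563, without YS-derived array 1). With only the groups compared in the fit, calls of Ct55, Ghr, Ly86 and Stap2 were lost too (adjusted p up to 0.216, 0.255, 0.35 and 0.192), as were calls of C2, Fsd2, Hnmt and Insl6 (up to 0.489, 0.155, 0.114 and 0.317). So were calls of the 5 lower genes just named (up to 0.372, 0.169, 0.169, 0.206 and 0.0742 in the same order) and 1 of Napsa, also lower in YS-derived cells (0.0507), while Cldn1 and Mbnl3 kept theirs in every fit. Clec1b was higher in AM-derived macrophages than in controls by 2.05 ± 0.28 and lower by -2.93 in FL-derived and -2.58 in YS-derived than in AM-derived macrophages, as it was higher in adult than in 6-week macrophages.

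Several lists gave few calls. None of the 7 Hox and adult haematopoietic genes was called between derived groups or against controls, and the lowest set adjusted p over 21 contrasts was 0.0968 with an estimated correlation. Of 5 T and NK cell genes 2 rose from yolk sac to YS-derived macrophages (2 adjusted over the list alone; adjusted p = 0.165 with an estimated correlation), led by Cd2 at 6.49 ± 0.19. The 3 B cell genes, the 2 of eosinophils, mast cells and basophils, the 4 of endothelium and the 10 of lung epithelium gave no called set test, with lowest adjusted p of 0.242, 0.341, 0.112 and 0.281 with an estimated correlation. The 4 sex-linked genes gave a called set test for BM-derived cells against controls at adjusted p = 0.0164, which was 0.105 with an estimated correlation.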
